A study of Mus musculus with 9 samples.

How the data were processed

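Gene expression was measured on 9 arrays of total RNA from R1E mouse embryonic stem cells: 3 arrays after transduction with a lentiviral short hairpin RNA against luciferase (shLuc) and 3 with each of 2 hairpins against Apela (shApela_1 and shApela_2). Groups and replicate numbers were taken from the sample titles. The labels do not say whether the repeats of a group were separate cultures or transductions, so p-values measure only the spread between these samples, which can be technical. The hairpin sequences and the time between transduction and RNA extraction are not given in the sources used here. The labels state that no drug was applied.

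The deposited table holds normalized log2 expression values, 1 per probe set and array, made with RMA (robust multi-array average) in Partek 6.6, per the submitters' processing notes. RMA combines the probes of a probe set after background correction and quantile normalization. Its version and settings, and the log base, are not given in the sources used here, and base 2 was read from the range of the values. Array medians lay between 7.03 and 7.12 with no missing value (0 of the table). Any pair of arrays held exactly equal values for between 1.19% and 7.54% of the genes, within and between groups alike, so equal values did not mark an array entered more than once. Scanner intensities and background levels were not used here, and the number of arrays limits the precision.

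The table held 28853 probe sets. GEO's platform annotation gave 21775 of them 1 gene symbol, 1578 several and 5500 none, and only the first kind was named. Of the named probe sets, 21684 matched a gene identifier in the RefSeq gene table of assembly GRCm38.p6, which was used for names only and changed 0 symbols. The 19938 genes were each represented by their brightest probe set (998 genes had more than 1). Trp53, Cdkn1a and Bax had no probe set with a single gene symbol and were not analysed here.

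Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, default prior, two-sided) in 1 fit of all 9 arrays, with 6 residual degrees of freedom and 2.72 from the prior. The 4 comparisons were each hairpin against shLuc, the mean of both hairpins against shLuc, and shApela_2 against shApela_1. Adjusted p-values are Benjamini-Hochberg values over the 19938 genes of a comparison, with a threshold of 0.05, and every adjusted p of a gene comes from limma. Changes are differences of log2 means with limma's standard error (SE), and group levels are means ± SD of 3 arrays.

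The text names the 10 largest rises and 10 largest falls of each hairpin and the 10 largest differences on each side between the hairpins, among genes past the threshold whose groups did not overlap on any array. It also draws on up to 4 members of each gene list past the threshold, or up to 2 with the smallest p where none passed, and on Apela, Apln, Aplnr and Hnrnpl. Predicted genes and small RNAs were left out. Where 5 or fewer genes passed in a comparison, all were named, which was added to the rule later.

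The 25 gene lists held 636 measured entries, from 3 to 36 per list. They covered p53 targets, intrinsic apoptosis machinery, DNA damage response, pluripotency, primed epiblast, the apelin ligands and receptor, the hnRNP family, small RNA machinery, S phase and DNA replication, G2 and mitosis, integrated stress and unfolded protein response, hypoxia response and glycolysis, cholesterol synthesis, imprinted genes, Nodal and TGF-beta targets, Wnt targets, heat shock response, immediate early genes and interferon response. The other 6 held markers of other cell types that a culture of embryonic stem cells can contain: primitive and definitive endoderm, primitive streak and mesoderm, neuroectoderm, trophectoderm, fibroblast feeder and two-cell-like. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 100 list tests, and again with the correlation estimated for each list and with fry. The groups, main tests, lists, alternatives and rule for named genes were chosen before the data were examined.

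Arrays with the same replicate number were checked for shared deviations from their group means. The correlations of shLuc with shApela_1 were 0.44, 0.40 and 0.68, and those of shApela_1 with shApela_2 were 0.18, 0.21 and 0.21, all over 0.1, so the numbers were taken to pair the arrays of those groups from the data alone. Those of shLuc with shApela_2 were -0.01, 0.67 and 0.47, which did not meet that rule. Alternatives were an intensity trend with a robust prior, leaving out dim genes (mean under the median probe set, 7.06), a second quantile normalization, centring of array medians, array weights, the replicate number as a block, only the compared arrays in the fit, every probe set or the mean of a gene's probe sets, stricter thresholds, 1 group of 6 hairpin arrays, and leaving out each array in turn. A fit of only the arrays numbered 1 and 2 was chosen after seeing the data.

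The fit was tested on simulated data: values of the 19938 genes were drawn independently around each gene's mean and spread, and 200 genes were given known changes, in 10 draws per comparison. For shApela_1 against shLuc it found 96.0% of 1.5-fold and 98.8% of 2-fold changes, with 4.57% false genes among its calls. For shApela_2 against shLuc it found 94.6% and 99.1%, with 4.53% false. The mean of both hairpins gave 96.9% and 99.7%, with 5.36% false, and the comparison of the hairpins 93.7% and 99.1%, with 4.78% false. With the p53 target list shifted by 0.1 (log2) in shApela_1, camera found it in 50 of 50 draws with the preset correlation and in 38 with the estimated one, with 8 and 0 false calls in 4400 tests of unchanged lists. Genes of these draws were uncorrelated, so false calls from correlated genes were not measured by it. The draws also held 200 changed genes, an equal spread of a gene on all arrays, no array apart and no effect of the replicate number. With fewer changed genes the adjusted threshold is stricter, so the shares found can be lower in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.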

Results

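Apela encodes a short secreted peptide that binds the apelin receptor. The title of the series presents its RNA as a regulator of cell death driven by p53, the DNA damage-responsive transcription factor, in embryonic stem cells. Expression was measured on Affymetrix arrays in R1E cells, a mouse embryonic stem cell line grown with 15% fetal bovine serum and 1000 units/ml of leukemia inhibitory factor, a cytokine that keeps the cells undifferentiated. The cells carried a lentiviral short hairpin RNA against luciferase (shLuc), which has no target in mouse cells, or 1 of 2 hairpins against Apela (shApela_1 and shApela_2). Each of the 3 groups had 3 arrays, 9 in all, and 19938 genes were tested. The design implies 4 comparisons: each hairpin against shLuc, both hairpins together against shLuc, and the hairpins against each other.

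Apela fell with both hairpins by about the same amount. Its log2 level was 11.30 ± 0.10 (SD, n = 3) in shLuc, 9.70 ± 0.06 in shApela_1 and 9.72 ± 0.14 in shApela_2, and all 6 knockdown arrays lay below all 3 control arrays. The change was -1.60 with shApela_1 (SE 0.08, adjusted p = 0.000197) and -1.58 with shApela_2 (SE 0.08, adjusted p = 0.000219), which left 32.9% and 33.4% of the control signal. Apela had the smallest p of all genes in both comparisons (rank 1). The hairpins differed in Apela by 0.02, with a 95% interval from -0.16 to 0.20. Where the probes of this probe set lie relative to the hairpin targets is not given in the sources used here.

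**Figure D1:**
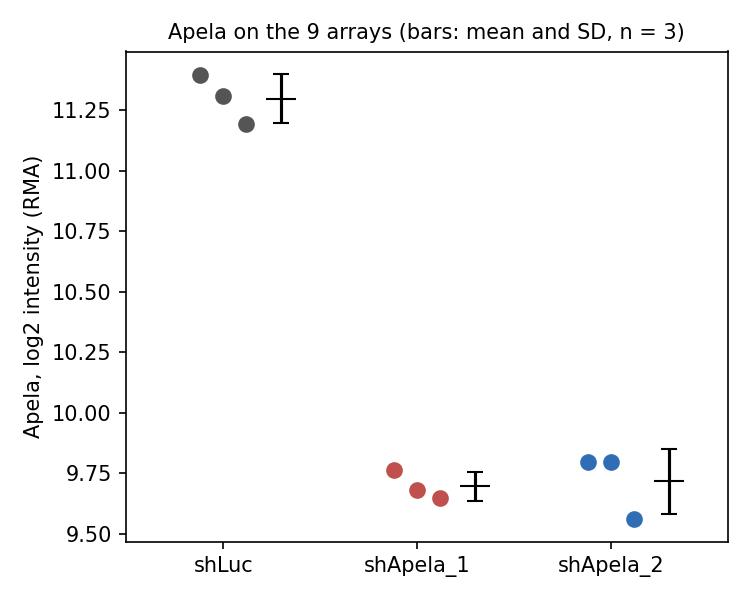
Log2 expression of Apela on each of the 9 arrays, by group, with the group mean and SD (n = 3). The shLuc arrays averaged 11.30, and the arrays of the 2 Apela hairpins averaged 9.70 and 9.72.

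The other members of the apelin system did not pass the test with either hairpin. Apln, the other ligand of the receptor, measured 7.14 ± 0.01 in shLuc and changed by -0.01 (adjusted p = 1) and 0.06 (adjusted p = 0.68) with shApela_1 and shApela_2 in limma. Aplnr, the apelin receptor, measured 6.48 ± 0.03 in shLuc, with differences of -0.00 (adjusted p = 1) and 0.15 (adjusted p = 0.68). Apln lay near and Aplnr below the median probe set of the table, 7.06. Hnrnpl, an RNA-binding protein of the hnRNP family, measured 11.19 in shLuc with differences of -0.00 (adjusted p = 1) and -0.01 (adjusted p = 0.93).

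The arrays were alike except for 1. The third shApela_2 array had a median of 7.12, where the other 8 lay between 7.03 and 7.07. Its interquartile range was 3.29 against 3.50 to 3.59, and its correlations with the other arrays were at most 0.995, below the lowest among the other 8 (0.996). The first principal component, with 47.3% of the variance, set this array apart. The second, with 21.5%, set the third arrays of shLuc and shApela_1 apart from the rest, and the next held 14.6%. Its Apela level, 9.56, lay with the knockdown arrays.

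**Figure D2:**
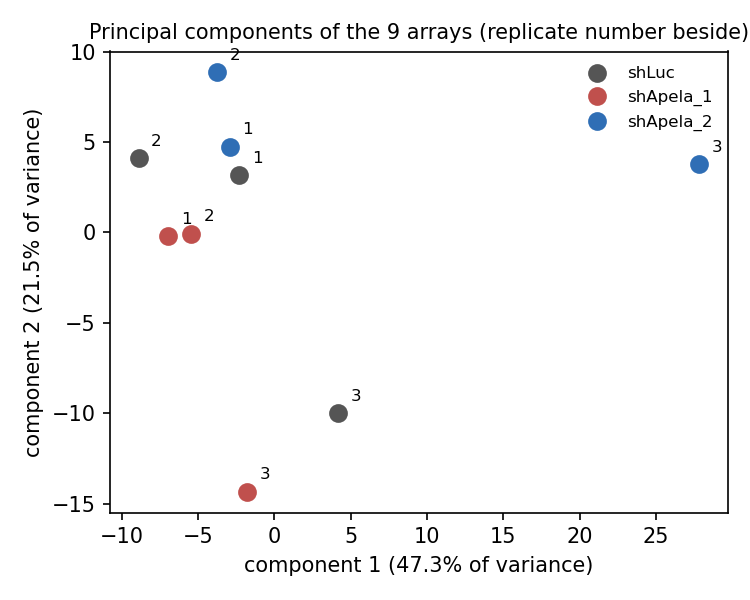
The 9 arrays on the first principal components of the 19938 genes, with the share of variance of each axis in percent and 1 point per array coloured by group. The third shApela_2 array stands apart on component 1 (47.3% of the variance).

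With shApela_1 67 genes changed, 28 upward and 39 downward. The largest rise was that of Cyp2b23, a cytochrome P450 gene, from 7.58 ± 0.14 to 8.79 ± 0.14 (1.21, SE 0.10, adjusted p = 0.00501). Notum, a secreted inhibitor of Wnt proteins, rose by 0.85 (adjusted p = 0.0494), Ampd3, an AMP deaminase, by 0.83 (adjusted p = 0.0367), and Pfn2, an actin-binding profilin, by 0.63 (adjusted p = 0.0207). Serpinb6c (0.63), P3h4 (0.56), the Ras-related GTPase gene Mras (0.46), Klhl42 (0.45), Ccdc85a (0.44) and Cyyr1 (0.42) rose as well, with adjusted p of at most 0.0498.

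After Apela, the largest fall with shApela_1 was that of Smc1b, a cohesin subunit of meiotic chromosomes, from 8.21 ± 0.16 to 7.20 ± 0.07 (-1.01, SE 0.16, adjusted p = 0.0494). Mael (-0.54, adjusted p = 0.00501) and Tdrd12 (-0.59, adjusted p = 0.0331), which act in the germline piRNA pathway that silences transposons, fell too. So did Saraf, a regulator of store-operated calcium entry (-0.88, adjusted p = 0.0134), the myosin phosphatase partner Mprip (-0.69, adjusted p = 0.00814), and the epithelial splicing regulator Esrp1 (-0.64, adjusted p = 0.0105). Vps35, a retromer subunit, fell by 0.56 (adjusted p = 0.00851), and Mknk2 (-0.52, adjusted p = 0.0134) and Dhx40 (-0.52, adjusted p = 0.0367) fell by similar amounts. Changes were small in general: 11 of the 67 genes reached 1.5-fold. The groups did not overlap for 13.7% of all genes, where chance gives 10% if arrays of different groups are unrelated, which arrays of equal number were not.

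The count for shApela_1 was sensitive to single arrays and to scaling. Leaving out an array gave 14, 4 and 20 genes without shLuc replicates 1, 2 and 3, 4, 3 and 21 without those of shApela_1, and 20, 16 and 146 without those of shApela_2, while all 67 genes kept their sign each time. Of the genes named for their size, only Apela and Cyp2b23 passed in all 9 of these fits. The replicate number as a block gave 190 genes, among them 65 of the 67. The split of 28 higher and 39 lower became 29 and 70 after a second quantile normalization and 10 and 21 after centring of array medians. That centring ended the calls of Notum, Ampd3, P3h4, Mras, Klhl42, Cyyr1, Smc1b and Dhx40 (adjusted p from 0.0572 to 0.087), as the second quantile normalization did for Notum, Mras and Cyyr1 (from 0.0588 to 0.0627).

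Targets of p53 shifted upward with shApela_1 at the preset correlation only. Of 36 measured targets 29 lay above their shLuc level and 7 below, with a median of 0.08 (camera, adjusted p = 0.00354, and adjusted p = 0.781 with an estimated correlation). Ptpn14, a tyrosine phosphatase, rose by 0.34 (adjusted p = 0.0367) and Phlda3, an inhibitor of AKT, by 0.28 (adjusted p = 0.0385). These were the 2 members past the test over all genes, and 2 passed when adjusted over the list alone. Both calls ended with centred medians (adjusted p = 0.0572 and 0.0522) and without any array but the third shApela_2 array (largest adjusted p = 0.199 and 0.198), and that of Phlda3 after a second quantile normalization (adjusted p = 0.0616). The list call ended without the first shApela_1 array (adjusted p = 0.072). The intrinsic apoptosis machinery had a median of 0.04 (26 genes, adjusted p = 0.177), and 0 of its members passed. Its smallest p belonged to Bak1, an effector of mitochondrial permeabilization, at 0.23 (adjusted p = 0.519).

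Several lists shifted downward with shApela_1 at the preset correlation. Trophectoderm markers, genes of the outer layer of the blastocyst, had a median of -0.13, and 20 of 23 were lower (camera, adjusted p = 0.000199, and adjusted p = 0.781 with an estimated correlation). Their lead members Bmp8b (-0.20, adjusted p = 0.262) and the keratin Krt8 (-0.49, adjusted p = 0.335, and 0.0263 with the replicate number as a block) did not pass over all genes, nor did any other (0 over all genes and 0 adjusted over the list alone). In the list of hypoxia response and glycolysis 28 of 33 genes were lower, with a median of -0.05 (adjusted p = 0.00091, and adjusted p = 0.781 with an estimated correlation). Its lead was the glucose transporter Slc2a1 at -0.30 (adjusted p = 0.0757, and 0.0263 with the block), the 1 member past the test adjusted over the list alone beside 0 over all genes. DNA damage response genes had a median of -0.05 with 22 of 32 lower (adjusted p = 0.00334, and adjusted p = 0.781 with an estimated correlation) and 0 members past either test; Xrcc5, which binds DNA ends, measured -0.24 (adjusted p = 0.411). Genes of G2 and mitosis had a median of -0.03 with 23 of 31 lower (adjusted p = 0.0172, and adjusted p = 0.804 with an estimated correlation), again with 0 members past either test and the kinetochore protein Cenpf at -0.25 (adjusted p = 0.18).

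The apelin list was also called (adjusted p = 0.00756, and adjusted p = 0.781 with an estimated correlation), but on Apela alone, the 1 member past either test: its mean was -0.54 and its median -0.01. The call of hypoxia response ended without the second shLuc array (adjusted p = 0.108), and that of G2 and mitosis without the second shLuc array (0.156) or the first shApela_1 array (0.0887). With the replicate number as a block, primed epiblast (median -0.12, adjusted p = 0.00312 against 0.14 without it) and integrated stress and unfolded protein response (median -0.03, adjusted p = 0.0485 against 0.227) joined the shApela_1 calls, with adjusted p = 0.8332 and 0.8335 in that fit with an estimated correlation. Uncalled on all arrays, 2 lists of markers passed downward without single arrays: fibroblast feeder (0.132) without the third shLuc (0.0125), first shApela_1 (0.039) or second shApela_1 array (0.0149), and primitive and definitive endoderm (0.135) without the third shLuc (0.0451) or second shApela_1 array (0.00185). With an estimated correlation their smallest adjusted p in these fits was 0.758 and 0.733.

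In the lists not called with shApela_1, single genes passed in 3. Raly, an hnRNP protein, fell by 0.50 (adjusted p = 0.00814) while the hnRNP family had a median of 0.00 (adjusted p = 0.868). Skil, a repressor of TGF-beta signalling, fell by 0.31 (adjusted p = 0.0472, and 0.0904 with centred medians) beside a median of -0.03 for Nodal and TGF-beta targets (adjusted p = 0.177). Notum was the 1 Wnt target that rose (list median 0.02, adjusted p = 0.97). Adjusted over the list alone, the counts were 1, 3 and 1. Pluripotency genes had a median of -0.03 (31 genes, adjusted p = 0.11), with 0 past the test over all genes and 2 adjusted over the list alone. Among them Lin28a, an RNA-binding protein that blocks let-7 processing, measured -0.44 (adjusted p = 0.064, and 0.0118 with the replicate number as a block). In the primed epiblast list, 0 members passed over all genes and 3 adjusted over the list alone. The carbonic anhydrase gene Car4 measured -0.55 there (adjusted p = 0.0558, 0.019 with the block and 0.0389 after a second quantile normalization) and the growth factor gene Fgf5 -0.47 (adjusted p = 0.117).

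With shApela_2 only 3 genes changed by limma, and all 3 fell (1151 genes at an unadjusted p under 0.05). Besides Apela, these were Mapre1, a protein of growing microtubule ends, from 10.08 ± 0.07 to 9.27 ± 0.14 (-0.81, SE 0.07, adjusted p = 0.0134), and Gorasp2, a Golgi stacking protein, from 10.81 ± 0.03 to 10.15 ± 0.03 (-0.67, SE 0.04, adjusted p = 0.000284). Neither moved with shApela_1, where Mapre1 measured 10.08 and Gorasp2 10.82 (adjusted p = 1 for each). The groups did not overlap for 10.3% of all genes, where chance gives 10% for unrelated arrays. Without the third shApela_2 array 6 genes passed, the same 3 and, chosen after their values were seen, Arhgef38 (0.51, adjusted p = 0.00326), Meiob (0.67, adjusted p = 0.0397) and Lrrc58 (-0.38, adjusted p = 0.0182). Mapre1 lost its call without any 1 of the shLuc arrays (adjusted p = 0.0805, 0.124 and 0.107 in the order of replicates), the first or second shApela_1 array (0.0557 and 0.0596) or the second shApela_2 array (0.0756). After a second quantile normalization 1 gene was higher and 6 were lower.

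Targets of p53 showed no shift with shApela_2 on all arrays: their median was 0.03 and 23 of 36 were higher (camera, adjusted p = 0.693). Without the third shApela_2 array the median was 0.06 (adjusted p = 0.00461, and adjusted p = 0.818 with an estimated correlation), so that 1 array decided the call at the preset correlation. On all arrays 0 targets passed the test of single genes, and the lead was Ak1, an adenylate kinase, at 0.21 (adjusted p = 0.638). The intrinsic apoptosis machinery had a median of -0.03 (adjusted p = 0.293) with 0 members past the test.

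With shApela_2, 4 lists shifted downward at the preset correlation only. DNA damage response had the smallest p, with a median of -0.04 and 28 of 32 genes lower (camera, adjusted p = 0.00149, and adjusted p = 0.781 with an estimated correlation). Heat shock genes, which encode chaperones, had a median of -0.04 with 15 of 18 lower (adjusted p = 0.0172, and adjusted p = 0.781 with an estimated correlation). Genes of S phase and DNA replication had a median of -0.02 with 25 of 32 lower (adjusted p = 0.0182, and adjusted p = 0.781 with an estimated correlation), and imprinted genes a median of -0.03 with 17 of 25 lower (adjusted p = 0.0392, and adjusted p = 0.781 with an estimated correlation). In these lists 0 members passed over all genes and 0 adjusted over the list alone. Their leads by p were the single-strand DNA-binding protein Rpa1 (-0.17), the chaperone partner Chordc1 (-0.19), the S phase cyclin Ccne2 (-0.34) and the imprinted Nnat (-0.19), each with adjusted p = 0.68. With shApela_2 0 lists were called after a second quantile normalization or with dim genes left out. The DNA damage call ended without the third shApela_2 array (adjusted p = 0.257). Deviations of that array from the mean of the other 8 went with brightness (Spearman -0.44 across genes). For the other 8 arrays, each set against the mean of all the rest, the value lay between -0.13 and 0.29. S phase lost its call without the third shLuc (0.186) or the second shApela_2 array (0.059), and heat shock without the same arrays (0.0636 and 0.0913). Imprinted genes lost theirs without the first or second shLuc array (0.127 and 0.108) or the first or second shApela_2 array (0.0534 and 0.117).

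Apela was the 1 gene past the threshold in the same direction with both hairpins. Independent lists of 39 and 3 falling genes would share 0.00587 genes. Since both hairpins were made against Apela, its place in both lists says nothing about other shared changes. Of the other 66 genes called with shApela_1, 45 had the same sign with shApela_2, against 56.5% of all genes. In limma 13 of the 45 had an unadjusted p under 0.05 with shApela_2. The shared shLuc arrays favour equal signs, so these counts cannot tell shared effects from shared controls. Taking the mean of both hairpins against shLuc, 3 genes passed, all lower (913 at an unadjusted p under 0.05): Apela (-1.59, adjusted p = 6.04e-05) and, chosen after their values were seen, Atp13a3 (-0.33, adjusted p = 0.0307) and Gorasp2 (-0.33, adjusted p = 0.0307). The calls of Atp13a3 and Gorasp2 ended with the replicate number as a block (adjusted p = 0.0943 for each) and without any array but the third shApela_2 array (adjusted p from 0.0747 to 0.301). Gorasp2 rested on shApela_2 alone, and Atp13a3, a polyamine transporter, measured 10.90 in shLuc, 10.40 in shApela_1 and 10.74 in shApela_2. The size for Atp13a3 depended on the probe set: the mean of its probe sets gave -0.54 (limma, adjusted p = 0.0308). Leaving out any array but the third shApela_2 array gave 1 gene, Apela, and leaving out that array gave 6, of which 3 were higher and 3 lower. The 3 rises, chosen after their values were seen, were Pfn2 (0.45, adjusted p = 0.00259), Arhgef38 (0.34, adjusted p = 0.0135) and Dpysl3 (0.34, adjusted p = 0.0399). After a second quantile normalization 2 genes were higher and 5 lower.

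**Figure D3:**
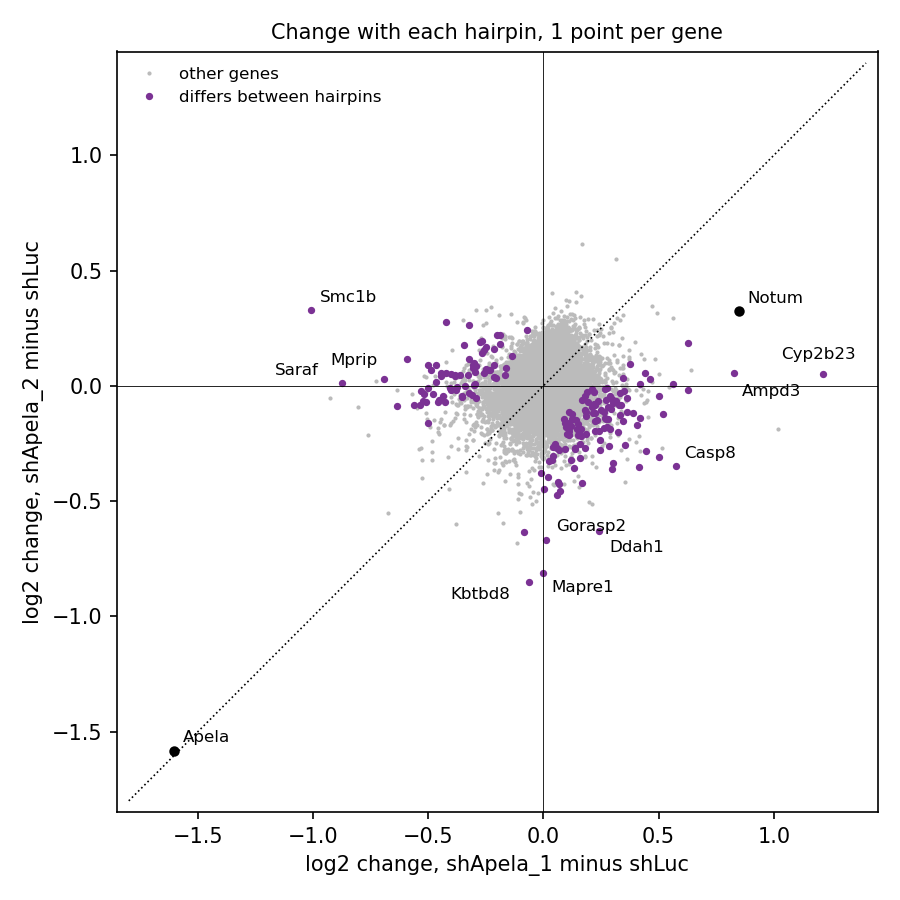
Log2 change against shLuc of each of the 19938 genes with shApela_1 (x axis) and shApela_2 (y axis), with the 189 genes that differ between the hairpins in purple, the other genes in grey, Apela and Notum in black, and a dotted line of equal change. Apela lies at -1.60 and -1.58, and the correlation across genes is 0.14.

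Across genes, the changes with both hairpins were weakly correlated (Pearson r 0.14, Spearman 0.15), where genes are not independent replicates. The shared shLuc arrays alone, simulated with unchanged groups and independent genes, gave r 0.50, and the same sign in 66.7% of genes against 56.5% observed. The observed covariance, 0.00134, lay below the simulated one, 0.00314. That simulation took the arrays of different groups as independent, while arrays of equal number deviated together (correlations from 0.40 to 0.68 for shLuc and shApela_1), which lowers the covariance expected from shared controls; with the effect of the replicate number removed, a model chosen after the values were seen, it was 0.00195. When the simulation kept the relations between genes on an array, its covariance had a median of 0.00258 with a range from -0.00357 to 0.0193. With 3 shLuc arrays, the controls could not be split into sets of at least 2. The correlation rose to 0.29 without the first shLuc array and was 0.07 without the second shApela_1 array.

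For the mean of both hairpins, the lists called were those of shApela_1. DNA damage response was lowest in p, with 26 of 32 genes lower and a median of -0.06 (camera, adjusted p = 4.15e-05, and adjusted p = 0.781 with an estimated correlation). Hypoxia response and glycolysis (-0.06, adjusted p = 0.00191), trophectoderm (-0.06, adjusted p = 0.00644) and G2 and mitosis (-0.01, adjusted p = 0.0255) were lower as well, with adjusted p = 0.781, 0.781 and 0.804 with an estimated correlation. Targets of p53 were higher, with 28 of 36 above shLuc (0.05, adjusted p = 0.0315, and adjusted p = 0.781 with an estimated correlation). For the apelin list, called downward (adjusted p = 0.0315, and adjusted p = 0.781 with an estimated correlation), the mean of -0.50 and the median of 0.03 differed in sign. Apela was the only member past the test over all genes in these 6 lists. Adjusted over the list alone, 2 p53 targets and Apela passed. Only the DNA damage call outlived every left-out array. Calls ended for p53 targets without the third shLuc (0.187), first shApela_1 (0.132), first shApela_2 (0.189) or second shApela_2 array (0.184), and for trophectoderm without the third shApela_1 array (0.0698). They ended for G2 and mitosis without the second shLuc (0.306), first shApela_1 (0.0696) or the third shApela_2 array (0.514), and for hypoxia response without the second shLuc (0.348) or the third shApela_2 array (0.0619). The apelin call ended without the first shLuc (0.0658), the third shApela_1 (0.077), first shApela_2 (0.0965) or second shApela_2 array (0.0574). Lists uncalled on all arrays passed downward without the third shLuc array (fibroblast feeder at 0.0482, cholesterol synthesis at 0.0472 and immediate early genes at 0.0286), the third shApela_1 array (heat shock at 0.0248) or the first shApela_2 array (pluripotency at 0.0442). With an estimated correlation 0 lists were called in any of these fits (adjusted p of at least 0.708).

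The hairpins differed from each other in 189 genes: 71 were higher with shApela_2 and 118 lower. Smc1b measured 8.54 ± 0.36 with shApela_2 and 7.20 ± 0.07 with shApela_1 (1.34, SE 0.16, adjusted p = 0.0107). Saraf (0.89), Mprip (0.72), Tdrd12 (0.71), Esrp1 (0.55) and the ascorbate transporter gene Slc23a1 (0.56) were likewise higher with shApela_2, all of them genes that fell with shApela_1 and stayed near shLuc with shApela_2. Slc46a3 (0.70), the imprinted zinc finger gene Peg3 (0.59), Zhx1 (0.59) and Fgf5 (0.56) were also higher with shApela_2, with adjusted p between 0.0283 and 0.0469. With centred medians Slc46a3 (adjusted p = 0.0604) and Zhx1 (0.069) lost their calls, and Fgf5 did after a second quantile normalization (0.062).

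On the other side, Cyp2b23 was lower with shApela_2 by -1.16 (adjusted p = 0.0044), and Ampd3 (-0.77) and Klhl42 (-0.73), which rose with shApela_1, were lower too. Casp8, the initiator caspase of death receptors, measured 7.15 ± 0.18 with shApela_1, 6.57 ± 0.10 in shLuc and 6.23 ± 0.13 with shApela_2, a difference of -0.92 between the hairpins (adjusted p = 0.00865), while neither passed against shLuc (adjusted p = 0.0716 and 0.68). Erbin, a scaffold protein (-0.81), and Fam171b (-0.77) had the same order. Mapre1 (-0.81), Gorasp2 (-0.68), Kbtbd8 (-0.79) and Ddah1, which degrades asymmetric dimethylarginine (-0.87), were lower with shApela_2. Of the 67 genes called with shApela_1, 49 also differed between the hairpins, as did 2 of the 3 called with shApela_2, and 138 of the 189 were called with neither.

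The groups did not overlap for 17.6% of all genes between the hairpins, where chance gives 10% for unrelated arrays, and 23 of the 189 reached 1.5-fold. The replicate number as a block gave 653 genes, among them all 189, and the fit of only the 6 hairpin arrays gave 28, where that of only the shLuc and shApela_1 arrays gave 44 for shApela_1, so the order of these counts turned. Leaving out an array gave 89, 92 and 115 genes without shLuc replicates 1, 2 and 3, 19, 20 and 81 without those of shApela_1, and 95 and 58 without replicates 1 and 2 of shApela_2. Of the genes named for their size, Cyp2b23, Mapre1, Fam171b, Klhl42, Gorasp2, Mprip and Slc23a1 passed in all 9 of these fits. The split of 71 higher and 118 lower became 134 and 120 after a second quantile normalization and 38 and 125 after centring of array medians.

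Between the hairpins 3 lists differed. Trophectoderm markers were higher with shApela_2, with a median of 0.12 and 22 of 23 genes above shApela_1 (camera, adjusted p = 0.0151, and adjusted p = 0.781 with an estimated correlation), and primitive streak and mesoderm markers had a median of 0.08 with 24 of 29 above (adjusted p = 0.039, and adjusted p = 0.848 with an estimated correlation). Genes of S phase and DNA replication had a median of -0.06 with 22 of 32 below (adjusted p = 0.0132, and adjusted p = 0.781 with an estimated correlation). Over all genes 0 members passed in these lists, and 5 S phase genes did when adjusted over the list alone, with Tk1, thymidine kinase, at -0.25 (adjusted p = 0.0712 over all genes, 0.0254 with the replicate number as a block and 0.0426 with centred medians). The streak and mesoderm call ended without the third shApela_2 array (0.685), on which the markers had a median of 0.21 above the mean of all other arrays. It also ended without the second shLuc (0.0568), the first shApela_1 (0.0598) or the third shApela_1 array (0.0725). Without the third shApela_1 array the calls of trophectoderm (0.0955) and S phase (0.139) ended too. Without the third shApela_2 array 5 lists differed: trophectoderm, S phase and, uncalled on all arrays, G2 and mitosis (0.05, adjusted p = 0.00112 against 0.311), hypoxia response (0.08, 0.00942 against 0.177) and pluripotency (0.06, 0.0159 against 0.421), all 3 higher with shApela_2. In that fit these 5 lists had adjusted p between 0.818 and 0.856 with an estimated correlation. Without the second shApela_1 array primitive and definitive endoderm (0.00333), fibroblast feeder (0.0289), hypoxia response (0.0437) and heat shock (0.0306) passed, without the first heat shock (0.0159), and without the third the intrinsic apoptosis machinery (0.0248), cholesterol synthesis (0.0465) and immediate early genes (0.00644). Without the first shApela_2 array the intrinsic apoptosis machinery (0.0351), two-cell-like (0.0262) and cholesterol synthesis (0.027) did. With an estimated correlation 0 lists were called in any of these fits (adjusted p of at least 0.708).

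Targets of p53 did not differ between the hairpins past the threshold (median -0.03, adjusted p = 0.0554, and 0.0133 with the replicate number as a block). Without the third shApela_2 array the adjusted p was 0.707 (median -0.00), and the list passed without the third shLuc (0.0478), second shApela_1 (0.0437), the third shApela_1 (0.00642), first shApela_2 (0.0199) or second shApela_2 array (0.0149). With an estimated correlation the adjusted p was 0.781 on all arrays, and 0 lists passed with the block or without any 1 array (adjusted p of at least 0.708). Ptpn14 was lower with shApela_2 (-0.31, adjusted p = 0.0277, ending in 6 of the 9 fits with an array left out), the 1 target past the test over all genes beside 3 adjusted over the list alone. The block also called the intrinsic apoptosis machinery (median -0.03, adjusted p = 0.0413 against 0.0659 without it), heat shock genes (-0.06, 0.0148 against 0.061), immediate early genes (-0.14, 0.0399 against 0.135), primed epiblast (0.17, 0.0188 against 0.293) and hypoxia response (0.05, 0.0482 against 0.177), which made 9 lists between the hairpins, and 0 with an estimated correlation (smallest adjusted p = 0.833). In lists that were not called, single genes differed: Lin28a (0.50, adjusted p = 0.0266), Raly (0.49, adjusted p = 0.00515) and Skil (0.27, adjusted p = 0.0443, and 0.103 with centred medians) were higher with shApela_2. The imprinted Nnat (-0.48) and Ndn (-0.41), each with adjusted p = 0.0158, and Bambi, a pseudoreceptor of the TGF-beta family (-0.34, adjusted p = 0.0496, and 0.0634 after a second quantile normalization), were lower.

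**Figure D4:**
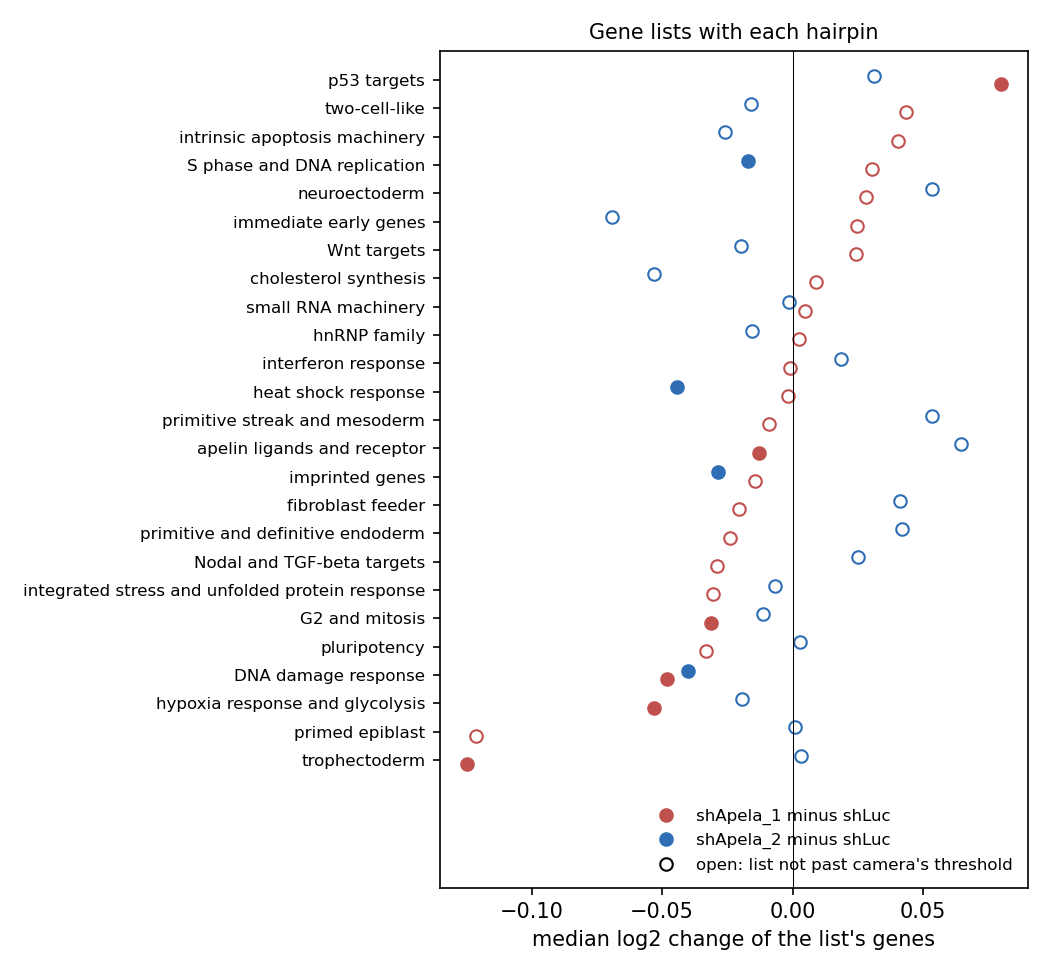
Median log2 change of each of the 25 gene lists with shApela_1 and shApela_2 against shLuc, filled where camera called the list at the preset correlation and open where it did not. With shApela_1 6 lists were called and with shApela_2 4, and none of them with an estimated correlation.

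The remaining lists did not pass in either comparison with shLuc, and none of their members did over all genes. Medians with shApela_1 and shApela_2 were -0.02 and 0.04 for primitive and definitive endoderm (adjusted p = 0.135 and 0.665), -0.01 and 0.05 for primitive streak and mesoderm (0.217 and 0.177), 0.03 and 0.05 for neuroectoderm (0.291 and 0.293) and -0.02 and 0.04 for fibroblast feeder markers (0.132 and 0.665). Of the feeder markers, the smooth muscle actin gene Acta2 measured -0.67 with shApela_1 (adjusted p = 0.576, and 0.0443 with the replicate number as a block) and the thrombospondin gene Thbs1 -0.41 (adjusted p = 0.641, and 0.0247 with the block). The two-cell-like list had 0.04 and -0.02 (0.704 and 0.173), with the transcript Tdpoz3 at 1.02 with shApela_1 (adjusted p = 0.168, and 0.0257 with the replicate number as a block). Interferon response genes had -0.00 and 0.02 (0.578 and 0.54), small RNA machinery 0.00 and -0.00 (0.818 and 0.388) and cholesterol synthesis 0.01 and -0.05 (0.997 and 0.202). Immediate early genes had 0.02 and -0.07 (0.861 and 0.0659). Of the lists called with 1 hairpin only, those of shApela_1 had medians with shApela_2 of -0.01 for G2 and mitosis (0.306), -0.02 for hypoxia response (0.173), 0.00 for trophectoderm (0.54) and 0.06 for the apelin list (0.177), and those of shApela_2 had medians with shApela_1 of 0.03 for S phase (0.355), -0.01 for imprinted genes (0.89) and -0.00 for heat shock (0.95). With shApela_2 the uncalled hnRNP family had -0.02 (0.0659, and 0.0187 with a median of -0.03 without the third shApela_2 array), integrated stress -0.01 (0.406), pluripotency 0.00 (0.587), primed epiblast 0.00 (0.86), Nodal and TGF-beta targets 0.03 (0.919) and Wnt targets -0.02 (0.813). Without other single arrays, lists uncalled with shApela_2 passed as well: hypoxia response without the first shLuc (0.0491), the third shLuc (0.0482) or second shApela_2 array (0.00328), immediate early genes without the third shLuc (0.00563), first shApela_2 (0.0325) or second shApela_2 array (0.0331), cholesterol synthesis without the third shLuc (0.0286) or first shApela_2 array (0.0153), two-cell-like without the first shApela_2 array (0.0255), and streak and mesoderm (upward, 0.0331) and G2 and mitosis (0.0214) without the second. With an estimated correlation none of the lists passed without any 1 array (adjusted p of at least 0.708). Median, mean and test differed in sign for the hnRNP family, cholesterol synthesis, imprinted genes, heat shock and immediate early genes with shApela_1. They also differed for pluripotency, primed epiblast, trophectoderm, fibroblast feeder, the apelin list, Nodal and Wnt targets with shApela_2.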

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

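Among the tests of this part, those of Apela's level, of the genes kept without 1 array and of the genes shared between comparisons were chosen after the 189 genes were seen.

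The test of the difference between the hairpins passed for 189 genes. Higher with shApela_2 than with shApela_1 (log2) were Smc1b (1.34), Saraf (0.89), Mprip (0.72), Tdrd12 (0.71), Slc46a3 (0.70), Peg3 (0.59), Zhx1 (0.59), Fgf5 (0.56), Slc23a1 (0.56), Esrp1 (0.55), Lin28a (0.50), Raly (0.49) and Skil (0.27). Lower were Cyp2b23 (-1.16), Casp8 (-0.92), Ddah1 (-0.87), Erbin (-0.81), Mapre1 (-0.81), Kbtbd8 (-0.79), Ampd3 (-0.77), Fam171b (-0.77), Klhl42 (-0.73), Gorasp2 (-0.68), Nnat (-0.48), Ndn (-0.41), Bambi (-0.34) and Ptpn14 (-0.31). Lists past the test at the preset correlation had medians of 0.0791 (primitive streak and mesoderm), 0.12 (trophectoderm) and -0.0561 (S phase and DNA replication), with adjusted p = 0.848, 0.781 and 0.781 with an estimated correlation. The streak and mesoderm call ended without the third shApela_2 array (adjusted p = 0.685), and all 3 calls ended without the third shApela_1 array (0.0725, 0.0955 and 0.139). Outside the named genes, 0 of 7078 probe sets with several or no gene symbols passed limma in any comparison (at an unadjusted p under 0.05, 338 with shApela_1, 349 with shApela_2, 293 for their mean and 440 between the hairpins).

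The 189 genes between the hairpins invite an explanation, since both hairpins lowered Apela. The tables argue against unequal knockdown, because Apela differed by 0.0200 with an interval from -0.16 to 0.20, small beside the mean fall of -1.59. They also argue against the third shApela_2 array alone, because 146 of the 189 genes stayed past the test without it. Targets of 1 hairpin other than Apela remain open: 49 of the 67 genes called with shApela_1 also differed between the hairpins, which such targets could give. So could a difference in virus dose, time or culture between the groups, and without the hairpin sequences these cannot be told apart. Both comparisons also share the shApela_1 arrays, so a gene with extreme values there tends to pass both. Against shLuc, 106 of the 189 genes had an unadjusted p under 0.05 with shApela_1 only, 30 with shApela_2 only, 51 with both in opposite directions and 2 with both in the same direction. Choosing genes that differ between the hairpins itself favours opposite over equal directions.

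The third shApela_2 array stood apart from the other 8. A narrower value range alone is argued against, because after a second quantile normalization its best correlation with another array was 0.996 (0.9958), still below the lowest among the other 8 (0.9964). A broad rise of markers of other cell types is argued against as well, by the medians of the 6 lists beyond genes of equal brightness. The highest lay 0.0684 above the mean of the other 8 arrays (primitive streak and mesoderm), or 0.21 without regard to brightness. A list median can miss a small share of other cells or a type outside the lists, so a smaller admixture stays open. A wrong hairpin label is argued against, because on 82.4% of 222 genes called between the hairpins without it the array lay nearer to the other shApela_2 arrays. RNA quality, hybridization and a different state of the cells stay open as untested causes.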

How the results depend on the processing

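Among the settings of this part, only the fit of the arrays numbered 1 and 2 was chosen after seeing the data. Apela stayed past the threshold in every fit with an array left out, from -1.66 to -1.55 with shApela_1 and from -1.64 to -1.50 with shApela_2 (largest adjusted p = 0.00416 and 0.00443), and was the gene shared by both hairpins each time. Leaving out each array gave 3 to 146 genes for shApela_1, 2 to 6 for shApela_2, 1 to 6 for their mean and 19 to 222 between the hairpins, a correlation of 0.0699 to 0.286, and 2 to 8 lists between the hairpins. Fewer arrays alone lower such counts, and the rise came without the third shApela_2 array. Of 52 called values of named genes other than Apela with either hairpin or between them, 10 stayed past the threshold in all 9 of these fits, 42 did not, and 0 reversed under any setting.

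With the replicate number as a block, counts were 190, 8 and 653 for shApela_1, shApela_2 and the hairpin difference, with 9 lists for the last, and 2 for the mean, of which only Apela was among its 3. Of those 52 calls of named genes, 52 stayed. Of 130 values not past the threshold, 19 passed. Apart from these, the shApela_1 and hairpin-difference calls already given, immediate early genes (shApela_2, adjusted p = 0.00196) and primed epiblast (mean of both hairpins, adjusted p = 0.0125), the block changed no other call of a list. With an estimated correlation the block called 0 lists in camera (smallest adjusted p = 0.833). Of shLuc and shApela_2 the first arrays, and of both hairpins the first and second, did not correlate best with their own number, so the block rests on a weaker pairing there. Array weights, which put the third shApela_2 array at 0.10, gave 688, 23, 31 and 1446 genes, 4 in both hairpins and a correlation of 0.25. The arrays numbered 1 and 2 gave 249 genes for shApela_1, 434 between the hairpins and a correlation of 0.28.

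An intensity trend with a robust prior gave 37 genes for shApela_1 and 5 lists between the hairpins. Centred medians gave 31 genes for shApela_1. A second quantile normalization gave 7 genes for shApela_2, 7 for the mean, 2 in both hairpins and 0 lists for shApela_2, as did leaving out dim genes for the lists (0). Only the compared arrays gave 44 genes for shApela_1 and 28 between the hairpins, with fewer samples behind the spread. Every probe set gave 6 lists between the hairpins, and the mean of a gene's probe sets 5. At least 1.5-fold left 11 genes for shApela_1, 1 for the mean and 23 between the hairpins, and adjusted p under 0.01 left 7, 1 and 27. The 6 hairpin arrays as 1 group gave 1 gene. An estimated correlation called 0 lists in each of the 4 comparisons, and fry 1, 1, 1 and 0, the apelin list each time. Apart from thresholds and fewer samples, the cause was not tested. Calls of named genes stayed for 44 of 52 (trend), 51 of 51 (dim genes out), 46 (quantile), 38 (centred), 25 (compared arrays), 49 (every probe set), 51 (mean of probe sets) and 48 (arrays 1 and 2). Background signal was not analysed here, so what dim probe sets can show stays unknown.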

Other observations

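Among the tests of this part, the germline list was written after Smc1b, Mael, Tdrd12 and Prss50 were seen among the falls with shApela_1. It left these genes out, and its tests were set before its values were seen, except for the fits of shApela_2 and of the hairpin difference without single arrays and the choice of Meiob, which came after.

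Germline genes, many of which embryonic stem cells transcribe at low levels, lay lower with shApela_1. Of 43 measured genes of meiosis and the piRNA pathway (46 were written), 38 were lower and 5 higher, with a median of -0.14. In limma 0 of them passed over all genes, where the germline genes seen among the falls had been left out beforehand, and 18 were lower at an unadjusted p under 0.05. Members singled out after their values were seen were Meioc (-0.80), Zcwpw1 (-0.73), Hormad1 (-0.64), the synaptonemal complex gene Sycp3 (-0.51), Mov10l1 (-0.45), Tex19.1 (-0.43) and the meiotic cohesin gene Stag3 (-0.40). With shApela_2 the median was -0.04, with 28 of 43 lower and 15 higher (5 and 1 at an unadjusted limma p under 0.05). Also chosen after their values were seen, Ddx4 (-0.24 with shApela_1 and -0.32 with shApela_2), Tex11 (-0.34 and -0.37), Stk31 (-0.33 and -0.23) and Slc25a31 (-0.28 and -0.31) fell with both hairpins. Meioc (-0.09), Zcwpw1 (0.02) and Hormad1 (-0.02) stayed near shLuc with shApela_2. For the mean of both hairpins, 33 of 43 were lower (camera with an estimated correlation, p = 0.00185), to which shApela_1 contributes. Between the hairpins the median was 0.09, with 36 higher in shApela_2. Outside the list, Smc1b measured 0.33 with shApela_2 (adjusted p = 0.68), Tdrd12 0.12 (0.68), Mael -0.08 (0.68), Prss50 -0.04 (0.83) and the meiotic gene Meiob 0.33 (0.686, and 0.67 with adjusted p = 0.0397 without the third shApela_2 array). Without that array the median of the list with shApela_2 was -0.03, with 24 of 43 lower (camera, p = 0.0266, and p = 0.167 with an estimated correlation), and it was -0.01, with 23 lower, without the third shLuc array (p = 0.0146 and 0.128) and -0.08, with 31 lower, without the first (p = 0.000805 and 0.0136).

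A wider fall of germline genes with shApela_1 is a hypothesis that these genes could have refuted and did not: camera gave p = 1.33e-16 with the preset correlation and p = 0.000891 with an estimated one for the median of -0.14, unadjusted for the 4 comparisons made. The list was measured on the same arrays as the genes that prompted it, so it is no independent replication. A difference between those arrays other than the hairpin would carry over to it. A shift common to genes of equal brightness is argued against, because the lowest median among 10000 random lists of equal brightness was -0.0345. Those lists were drawn gene by gene, so they cannot stand for related genes that move together. A single array is argued against too, because the median stayed between -0.18 and -0.12 (-0.124 at the nearest to 0) with each of the 9 arrays left out, with p from 0.000227 to 0.00278. With shApela_2 camera gave p = 0.00394 with the preset correlation and p = 0.0781 with an estimated one (0.0136 to 0.167 with an array left out) for the median of -0.04. Of 10000 random lists of equal brightness 0 were as low, which cannot decide this, because such lists leave out the relations between genes. The difference between the hairpins gave p = 0.02 in camera with an estimated correlation (0.056 and 0.0668 without the first or second shApela_2 array). Whether the list falls with shApela_2, and whether Apela or another target of shApela_1 is behind the fall, thus stays open. Over the 10 splits of the shLuc and shApela_1 arrays, too few for a share under 0.05, the size of the real median was 0.139 and the highest other 0.0953.

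Other splits of the arrays were fitted for each count. For shApela_1 against shLuc the real split gave 67 genes and the highest other 0 (1 of 10 splits as large), for shApela_2 against shLuc 3 and 0 (1 of 10), and between the hairpins 189 and 0 (1 of 10), where 4 of the 10 splits parted all 3 pairs of equal number and the highest other of these was also 0. For called lists the real and highest other counts were 6 and 9 (5 of 10 splits as large), 4 and 9 (10 of 10) and 3 and 10 (10 of 10), and among the 4 splits that parted all pairs the highest others were 4, 6 and 9. In each of these, 10 splits are too few for a share under 0.05. For the mean of both hairpins, 100 splits of all 9 arrays were taken, the real one and others drawn at random. Counts out of these 100 include the real split. As many as 3 genes came from 2 of them, yet the highest other split called 144 genes, which points to a structure among the arrays. The 1 gene changed in the same direction came from 4 of the 100 splits, with 28 as the highest other, and the 6 called lists from 49, with 10 as the highest other. These splits disregard the replicate numbers. Among 100 of the 108 splits that give each group 1 array of each number, as the real one does, drawn after the other counts were seen, 6 had as many as 3 genes (highest other 200), 11 a gene changed in the same direction (49) and 38 as many lists (10). Chance was thus not excluded for any of these counts by the splits that keep the numbers. The splits that disregard them cannot exclude it, because arrays of equal number deviated together in most pairs of groups. Both kinds of split also mix hairpins that differ in 189 genes, so they do not stand for unchanged arrays. The 1 gene changed in the same direction was Apela, and its own values argue against chance. It changed by -1.60 and -1.58 with the 2 hairpins (limma, adjusted p = 0.000197 and 0.000219).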
